A study of Mus musculus with 22 samples.

How the data were processed

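Cells of the mouse retina were collected after sorting, per the labels, as rods, cones, bipolars, rod bipolars and cone bipolars, at P7, P13 and P30 for the first 3 types and at P13 for the bipolar subtypes. RNA was isolated and amplified in a linear fashion, and libraries were made with a TruSeq kit, per the labels. The labels give age, tissue and cell type for each of the 22 libraries and no batch. Per the submitters' processing notes, reads were aligned with STAR to GRCm38 (mm10) and processed with edgeR, with no version given for either. The read counter, the gene annotation and the gene filter of the authors are not given in the sources used here.

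The deposited table holds log2 CPM (counts scaled to library size) for 13812 Ensembl genes and 22 libraries, and the file name and the values are the source of that unit. A gene with no reads has the same value, -7.10, in every library, so a small prior was added before the log. Once that floor was taken off on the linear scale, 100.0% of the values lay within 0.0100 of a whole number of reads. The recovered totals ran from 14.4 to 54.4 Mreads, and the deposited values were scaled by effective library sizes, 0.608 to 1.23 times the totals. The number of genes with no reads ran from 174 to 2463 per library. The floor of 3 reads lay between 0.0540 and 0.170 CPM for single libraries, and floors in the text are taken over both libraries of a group. Symbols and positions came from GENCODE M21, which matched 13785 of the IDs. The 27 IDs without a symbol were left out, and held 0.109% of reads overall and at most 0.378% of a library.

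Tests were run in R 4.3.3 with limma 3.58.1 on the deposited log2 values. A gene was tested if its log2 CPM was at least 0 in both libraries of at least 1 group, which left 13405 genes and took out 380. All 22 libraries entered 1 linear model with a coefficient per group, 11 residual degrees of freedom and empirical Bayes moderation with an intensity trend (4.27 prior degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.0500 over all genes tested and a log2 fold change of at least 1 in either direction. The 15 comparisons were rods against cones and bipolars against the mean of rods and cones at each age, successive ages within rods, cones and bipolars, rod bipolars against cone bipolars at P13, and interactions of the P7 to P30 change between rods and cones and between bipolars and photoreceptors. Enriched genes were called higher in 1 of rods, cones and bipolars than in each of the others at all 3 ages. limma was used since the table holds log2 CPM and no counts, and the recovered reads served floors, read shares and added alternatives.

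The comparisons, thresholds, filter, 37 gene lists, the rule for named genes and the alternatives to be tried were fixed before the data were examined. Each list was tested with camera at a preset correlation of 0.0100 and again with an estimated correlation, adjusted by Benjamini-Hochberg over the lists of a comparison. Of 555 list tests, 176 were called with the preset correlation and 38 of these also with the estimated one. These were the cone phototransduction list for rods against cones at each age, the rod bipolar markers for rod against cone bipolars, and the ribbon synapse list for bipolars from P7 to P13. For bipolars from P13 to P30 they were the cone phototransduction, Müller glia, immature neuron and stress lists. For bipolars against photoreceptors they were the rod, shared, outer segment and immature neuron lists at each age, the cone phototransduction and ribbon synapse lists at P7, the pan-bipolar, rod bipolar, cone bipolar, cadherin, Eph, neurexin and GABA receptor lists at P13 and P30, and the leucine-rich repeat list at P30. The lists covered rod, cone, shared photoreceptor and outer segment genes, pan-bipolar, mGluR6 cascade, OFF-bipolar, rod bipolar and cone bipolar genes, markers of Müller glia, amacrine, ganglion, horizontal, microglial, vascular, pigment epithelium and red blood cells, proliferation, immature neurons, Wnt ligands, Wnt receptors and Wnt modulators, cadherins, semaphorins, ephrins, slits and netrins, leucine-rich repeat proteins, immunoglobulin superfamily adhesion, neurexins, the ribbon synapse, GABA and glycine receptors, glutamate receptors, glycolysis, the respiratory chain, cholesterol synthesis, stress genes and chromatin regulators.

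Named genes were, per comparison, the 10 called genes with the largest rise and the 10 with the largest fall whose groups did not overlap and whose mean log2 CPM in the higher group was at least 3, up to 6 called members per list, and a fixed set that included Nrl, Opn1sw, Arr3, Grm6, Wnt5a, Wnt5b and Ryk. Some genes that this rule names, and 1 test of rod RNA in cone libraries that rests on such a gene, are not reported here. The text leaves out genes that the rule allows, chiefly those that lost a call when 1 library was left out or under an alternative, and those with at most 3 reads in a group.

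The test was run on simulated data with 100 genes planted at each size of change. Each gene had the same spread relative to its level in all groups. In the data the median SD of replicates ran from 0.130 in bipolars at P7 to 0.492 in rods at P13. The rates below hold for the simulated setting and may differ in the comparisons themselves. For rods against cones at P13 it recovered 55% of changes of log2 1.5 and 89% of log2 3, and 12.2% of all calls were false. For cones from P7 to P13 the values were 47%, 87% and 5.63%, for rod against cone bipolars 54%, 86% and 14.1%, and for bipolars from P13 to P30 62%, 86% and 10.8%. Each false share lay above the adjusted p threshold of 0.0500. No recovered gene had the wrong sign. The alternatives were no filter, a filter at log2 CPM 2, quantile normalization, centring on the median of the tested genes, log2(CPM + 1), no intensity trend, robust moderation, array quality weights, only the compared groups in the fit, no fold threshold, the replicate number as a block, and each library left out in turn, with the other library of its group assumed to vary like the other groups. Precision weights from the recovered reads (limma voom), scaling by plain read totals, and leaving out transcripts of the mitochondrial genome were chosen after seeing the data.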

Results

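Messenger RNA was sequenced from cells purified from the mouse retina: rods and cones, the photoreceptors that detect light, and bipolar cells, the interneurons that take up their signal. Rods, cones and bipolars were each collected at postnatal days 7, 13 and 30 (P7, P13 and P30), and rod bipolars and cone bipolars, the bipolar classes that contact rods and cones, at P13. Each of the 11 groups had 2 libraries, 22 in all. As known of the study, it asked which surface and secreted molecules mark each cell type while photoreceptors and bipolars form synapses. The sample labels say bipolars, and the series design calls these cells ON-bipolars.

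The libraries held 14.4 to 54.4 megareads (Mreads) over the genes of the table. Mean depth was 44.1, 39.9 and 49.02 Mreads in rods at P7, P13 and P30. In cones it was 48.2, 46.8 and 44.4 Mreads and in bipolars 15.9, 17.02 and 27.4 Mreads. Rod bipolars had 22.7 Mreads and cone bipolars 21.9 Mreads. A gene with no reads in either library of a group could lie as high as 3 reads over that group. In CPM (counts scaled to library size) that floor was 0.0275 CPM in cones at P7 and 0.0766 CPM in bipolars at P7. These floors cover counting error only, since the RNA was amplified before sequencing. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between libraries, which may be technical. The correlation of replicates across genes, which are not independent, ran from 0.849 in cones at P30 to 0.971 in bipolars at P7. The first principal component held 43.4% of the variance and set every bipolar-type library apart from the rods and cones. The second, with 11.4%, set cones apart from rods. Differences are given as log2 fold changes ± SE from limma with 2 libraries per group, and levels as mean CPM ± SD over those libraries. The SE rests on 1 spread per gene pooled over all 11 groups, so it is the same at each age. The median SD of replicates on the log2 scale ran from 0.130 in bipolars at P7 to 0.492 in rods at P13. The pooled SE thus overstates the spread of the quieter groups and understates that of the noisier ones.

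**Figure D1:**
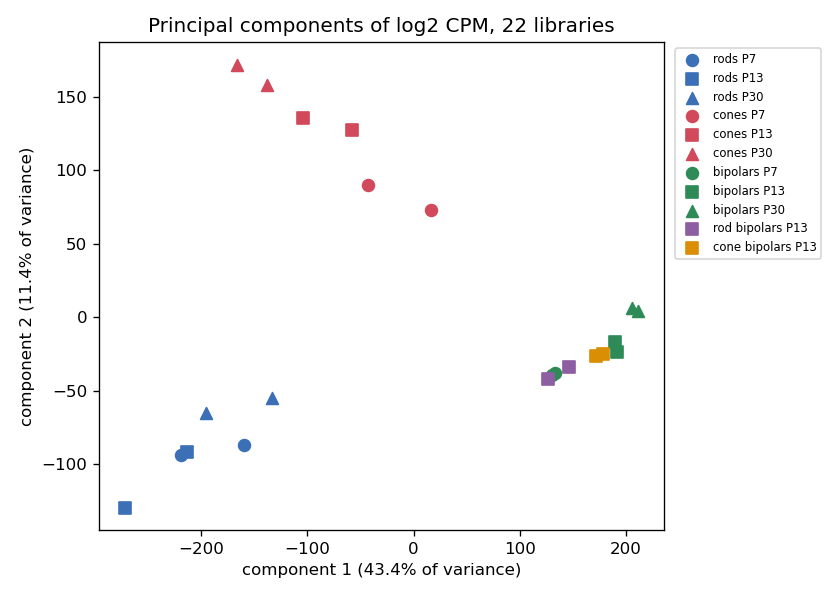
Principal components 1 and 2 of the deposited log2 CPM values, 1 point per library, with colour for cell type and marker shape for age. The bipolar-type libraries lie at positive values of component 1, and the cone libraries lie above the rod libraries on component 2.

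Rods and cones were compared at each age. Most members of the rod phototransduction list were higher in rods, and most of the cone list higher in cones, at P7, P13 and P30. Nrl (chromosome 14, 55518978 to 55524981, 1-based on GRCm38 as are all coordinates here), the transcription factor that directs the rod fate, was higher in rods by 4.53 ± 0.40 at P7, 4.22 ± 0.40 at P13 and 4.97 ± 0.40 at P30. Its levels were 1055 ± 199, 689 ± 24.6 and 746 ± 5.99 CPM in rods at P7, P13 and P30. In cones they were 46.96 ± 18.4, 37.04 ± 1.95 and 24.5 ± 8.07 CPM. Opn1sw (chromosome 6, 29376671 to 29388468), the short-wavelength cone pigment gene, was lower in rods, at -10.44 ± 0.86, -9.75 ± 0.86 and -9.05 ± 0.86. Its levels in cones were 3846 ± 139, 7232 ± 411 and 10333 ± 729 CPM. Arr3 (chromosome X, 100605497 to 100618493), which encodes cone arrestin, had 2159, 5999 and 11516 CPM in cones. In rods it had 0.317, 17.1 and 32.9 CPM.

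The list of rod phototransduction genes and rod regulators had 13 of 18 members higher and 1 lower (14 higher and 1 lower adjusted over the list alone) in rods at P7. At P13 it had 16 of 18 members higher (the same adjusted over the list alone), and at P30 14 of 18 members higher (the same adjusted over the list alone). The list was called at P7 (camera adjusted p = 2.6e-19, adjusted p = 0.062 with an estimated correlation). It was also called at P13 (camera adjusted p = 6.1e-18, adjusted p = 0.08 with an estimated correlation) and P30 (camera adjusted p = 1.4e-13, adjusted p = 0.2 with an estimated correlation). Among its members, Cngb1, a subunit of the rod cyclic nucleotide-gated channel, differed by 5.05 ± 0.33, 5.31 ± 0.33 and 5.08 ± 0.33. Pde6b, a catalytic subunit of rod phosphodiesterase, differed by 4.96 ± 0.38, 5.03 ± 0.38 and 5.65 ± 0.38. Nr2e3, a rod nuclear receptor that represses cone genes, differed by 4.99 ± 0.54, 5.25 ± 0.54 and 5.81 ± 0.54. The member that was lower in rods at P7 was Guca1b, a guanylate cyclase activator, named after its values were seen. It stood at 9.11 CPM in rods and 205 CPM in cones. The cone phototransduction list had 12 of 14 members lower (13 lower adjusted over the list alone) in rods at P7 (camera adjusted p = 3.4e-16, adjusted p = 4.1e-04 with an estimated correlation). At P13 it had 14 of 14 members lower (the same adjusted over the list alone), and at P30 13 of 14 members lower (14 lower adjusted over the list alone). Gnat2, the cone transducin gene, had 4139 and 0.199 CPM in cones and rods at P13. Gngt2, the cone transducin gamma gene, was lower in rods at P30, with a log2 fold change of -8.86 ± 0.41. The list of genes shared by both photoreceptor types had 6 of 27 members higher and 2 lower (7 higher and 3 lower adjusted over the list alone) in rods at P7. At P13 it had 9 of 27 members higher and 1 lower (10 higher and 1 lower adjusted over the list alone) (camera adjusted p = 0.0017, adjusted p = 0.48 with an estimated correlation), and at P30 6 of 27 members higher and 1 lower (7 higher and 1 lower adjusted over the list alone). Pdc, phosducin, differed by 2.96 ± 0.38 and 2.42 ± 0.38 at P7 and P13, and Prph2, a disc rim protein, by 1.91 ± 0.32 and 1.72 ± 0.32. The outer segment and connecting cilium list had 5 of 30 members higher (the same adjusted over the list alone) at P7. At P13 it had 8 of 30 members higher and 1 lower (the same adjusted over the list alone) (camera adjusted p = 0.0026, adjusted p = 0.2 with an estimated correlation), and at P30 9 of 30 members higher and 1 lower (the same adjusted over the list alone). Rp1, an axonemal protein of the outer segment, was higher in rods at every age (2.86 ± 0.42, 2.73 ± 0.42 and 2.95 ± 0.42), as was Prom1, prominin of the disc rim, at P7 (1.81 ± 0.26).

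**Figure D2:**
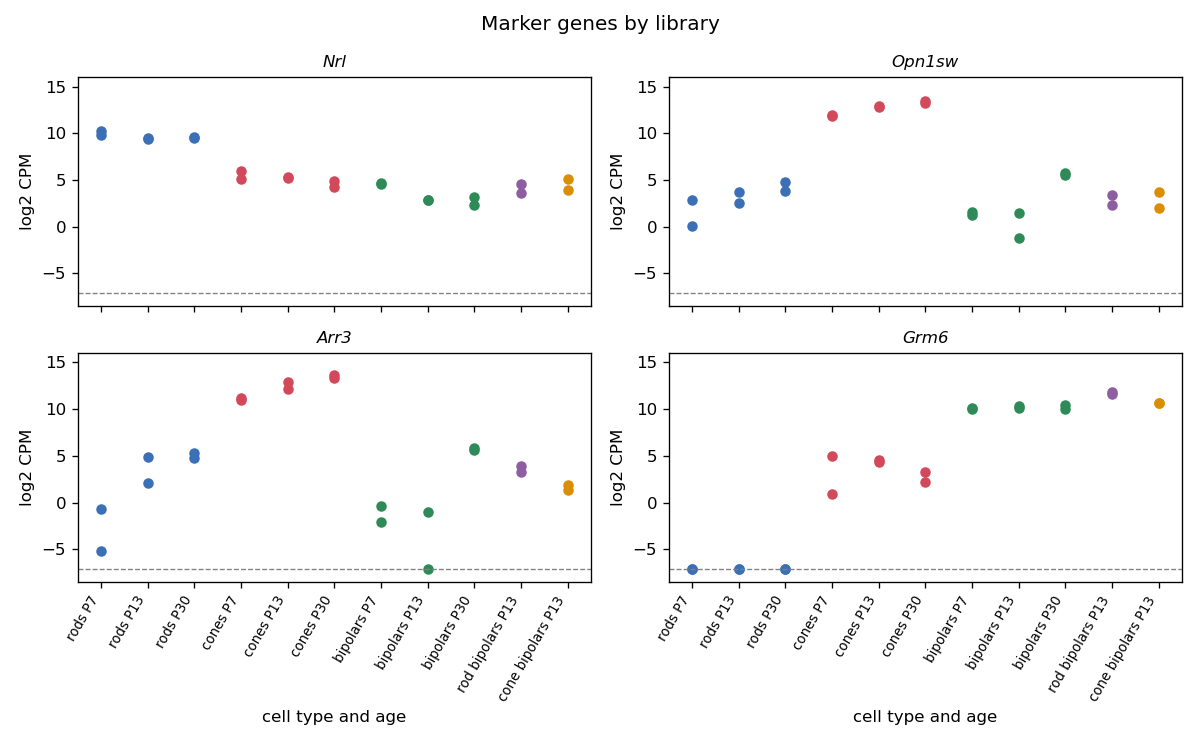
Deposited log2 CPM of Nrl, Opn1sw, Arr3 and Grm6 in each library, 1 point per library, by cell type and age on the horizontal axis. Points at the dashed line have no reads. Nrl is highest in rods, Opn1sw and Arr3 in cones, and Grm6 in the bipolar-type groups.

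Cones held more of several transcripts that also mark bipolars. The pan-bipolar list had 1 of 19 members higher and 5 lower (1 higher and 12 lower adjusted over the list alone) in rods at P7 (camera adjusted p = 7.7e-05, adjusted p = 0.23 with an estimated correlation). At P13 it had 1 of 19 members higher and 9 lower (1 higher and 10 lower adjusted over the list alone), and at P30 7 of 19 members lower (8 lower adjusted over the list alone). The ON-bipolar mGluR6 cascade list had 5 of 12 members lower (7 lower adjusted over the list alone) at P7 (camera adjusted p = 7.7e-05, adjusted p = 0.17 with an estimated correlation) and 5 of 12 members lower (7 lower adjusted over the list alone) at P13. Cabp5, a calcium-binding protein, had 211 CPM in cones and no reads in rods at P7, at least 6717-fold higher. At P30 it had 1.13 and 291 CPM in rods and cones (-8.08 ± 0.72). Gnb3, a G protein beta subunit that cones and ON-bipolars share, was lower in rods, with a log2 fold change of -1.98 ± 0.22, -4.19 ± 0.22 and -3.95 ± 0.22. Gnao1, the G protein of the mGluR6 cascade, differed by -1.73 ± 0.27, -2.38 ± 0.27 and -1.82 ± 0.27. Grm6 (chromosome 11, 50850685 to 50866208), the mGluR6 receptor gene itself, had no reads in rods and 16.7 ± 20.98 CPM in cones at P7, against 1089 ± 47.0 CPM in bipolars. Prkca, the kinase used to label rod bipolars, was higher in rods than cones at P13 (4.06 ± 0.68).

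Members of several families of surface molecules differed between rods and cones. Leucine-rich repeat synaptic proteins had 9 of 37 members lower (11 lower adjusted over the list alone) in rods at P7. At P13 they had 1 of 37 members higher and 15 lower (the same adjusted over the list alone) (camera adjusted p = 0.0024, adjusted p = 0.31 with an estimated correlation). Lrfn2, a synaptic adhesion protein, had 59.9 CPM in cones and 0.348 in rods at P30 (-7.44 ± 1.12). Neurexins, neuroligins, teneurins and latrophilins had 6 of 23 members lower (the same adjusted over the list alone) at P13 (camera adjusted p = 0.014, adjusted p = 0.48 with an estimated correlation). At P30 they had 1 of 23 members higher and 6 lower (the same adjusted over the list alone). Nrxn3, a presynaptic neurexin, was lower in rods, with a log2 fold change of -2.76 ± 0.53 at P13 and -5.35 ± 0.53 at P30. Clstn3, a calsyntenin that binds neurexins, differed by -1.84 ± 0.32 and -2.98 ± 0.32. Tenm4, a teneurin, had 67.7 CPM in cones with no reads in rods at P13. At P30 it had 71.4 against 0.491 CPM (-7.20 ± 0.33). The immunoglobulin superfamily had 8 of 43 members higher and 8 lower (9 higher and 11 lower adjusted over the list alone) in rods at P30, with a list median that turned from negative to positive with scaling by plain read totals. Jam3, a junctional adhesion molecule, had 3.73 CPM in rods and 739.9 in cones (-8.41 ± 1.33). Nfasc, neurofascin, was higher in rods (5.14 ± 0.44). Cadherins and protocadherins had 6 of 24 members lower (the same adjusted over the list alone) at P7 (camera adjusted p = 0.0041, adjusted p = 0.15 with an estimated correlation). Pcdh15, the Usher syndrome protocadherin, differed by -1.25 ± 0.21 at P7 and -1.74 ± 0.21 at P30. Epha10, an Eph receptor, had 84.8, 84.8 and 72.1 CPM in cones. In rods it had 0.127, 0.0980 and 0.530 CPM. GABA and glycine receptors had 9 of 21 members lower (12 lower adjusted over the list alone) at P7 (camera adjusted p = 1.2e-06, adjusted p = 0.062 with an estimated correlation). At P13 they had 7 of 21 members lower (9 lower adjusted over the list alone). At the synaptic terminal, Cplx3, a complexin of ribbon synapses, was lower in rods, with a log2 fold change of -3.22 ± 0.22 at P13 and -4.91 ± 0.22 at P30. Wnt receptors and planar polarity genes had 4 of 25 members higher and 4 lower (the same adjusted over the list alone) at P30, with a positive median and a negative mean over the list. Prickle2, a planar polarity protein, had 1.42 CPM in rods and 162 in cones (-8.26 ± 1.28).

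In energy metabolism, Hk2, the hexokinase of photoreceptors, was lower in rods at P7 (-5.22 ± 0.34) and P13 (-2.93 ± 0.34). Eno2, a neuronal enolase, was lower as well (-1.68 ± 0.20 and -1.95 ± 0.20), and Ldha, lactate dehydrogenase A, was higher at P7 (1.47 ± 0.21). The nuclear genes of the mitochondrial respiratory chain had 6 of 43 members higher (the same adjusted over the list alone) in rods at P7 (camera adjusted p = 1.0e-10, adjusted p = 0.44 with an estimated correlation). At P30 they had 14 of 43 members lower (the same adjusted over the list alone) (camera adjusted p = 3.1e-07, adjusted p = 0.56 with an estimated correlation). Cox8a, a cytochrome c oxidase subunit, differed by -2.38 ± 0.27 at P30. Transcripts of the mitochondrial genome took 2.69%, 6.92% and 8.13% of reads in rods at P7, P13 and P30. In cones they took 5.37%, 17.5% and 33.6%. Chromatin regulators had 5 of 26 members higher and 1 lower (the same adjusted over the list alone) in rods at P30, among them Hmgn2, a nucleosome-binding protein, at 1.88 ± 0.26. Tet1, a methylcytosine dioxygenase, was lower at P13 (-4.73 ± 0.68) and P30 (-3.90 ± 0.68). Cholesterol synthesis genes had 1 of 19 members higher and 3 lower (1 higher and 2 lower adjusted over the list alone) at P13. Of all 13405 tested genes, 952 were higher and 1891 lower in rods at that age. Markers of other cells and signs of handling went with these groups too. Egr1, an immediate early gene, had 1325 ± 779 CPM in cones and 27.05 ± 1.94 CPM in rods at P7 (-5.48 ± 0.90). Clu, a Müller glia marker, was lower in rods at each age (-2.41 ± 0.40, -2.69 ± 0.40 and -3.65 ± 0.40). Red blood cell genes had 4 of 4 members lower (the same adjusted over the list alone) in rods at P30 (camera adjusted p = 0.017, adjusted p = 0.52 with an estimated correlation).

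Between rods and cones, limma with Benjamini-Hochberg adjustment called 1718 of 13405 tested genes at P7 (442 higher and 1276 lower in rods). It called 2843 at P13 (952 and 1891) and 2684 at P30 (1338 and 1346). Of the genes lower in rods, 436, 407 and 86 at P7, P13 and P30 had no reads in either rod library. Of those higher in rods, 3, 48 and 263 had none in either cone library. Mean genes detected per library were 11745, 11602.5 and 12623.5 in rods and 13287, 12435.5 and 11719 in cones. Whether loss of low transcripts from some libraries produced part of these calls was not tested. The split at P30 moved to 3090 and 833 with plain read totals and 1595 and 1191 without mitochondrial genome transcripts. Without cones P7 replicate 1 the P7 count was 923 and without replicate 2 1038. With only the compared groups in the fit the counts at P13 and P30 were 491 and 863. Gnao1, Ldha and Prph2 at P7 were not called in that fit, in which 12 of 22 genes named at P13 and 15 of 26 at P30 kept their calls. With array quality weights the count at P13 was 1295, and Arr3 and Prph2 were not called.

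Bipolars were compared with the mean of rods and cones at each age. Bipolars held the transcription factors and the glutamate-sensing cascade of bipolar cells, and far less of the phototransduction and outer segment genes. Grm6 had 1191 ± 107 CPM in bipolars at P13 and 1191 ± 225 at P30. It had no reads in rods, so it was at least 38909-fold higher in bipolars at P30, and 7.20 CPM in cones. Isl1, a LIM homeobox factor of ON-bipolars, was higher by 8.96 ± 1.61, 10.63 ± 1.61 and 12.73 ± 1.61 at P7, P13 and P30. Its level in bipolars was 984, 842 and 577 CPM, so the larger estimates at later ages did not come from a rise in bipolars. With an SE of 1.61 at each age, these estimates do not settle whether the difference changed.

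Members of each photoreceptor list were lower in bipolars. The rod list had 18 of 18 members lower (the same adjusted over the list alone) at P7 and 17 of 18 members lower (the same adjusted over the list alone) at P30. The shared list had 26 of 27 members lower (the same adjusted over the list alone) at P13. The outer segment list had 23 of 30 members lower (the same adjusted over the list alone) at P30. Examples at P30 were Sag, rod arrestin, at -6.29 ± 0.28, Tulp1, at -6.65 ± 0.37, and Rp1, at -8.11 ± 0.36. Aipl1, the chaperone of phosphodiesterase, stood at -8.24 ± 0.24 at P7. The cone list had 1 of 14 members higher and 9 lower (1 higher and 10 lower adjusted over the list alone) at P7 (camera adjusted p = 2.1e-04, adjusted p = 0.031 with an estimated correlation). At P30 it had 1 of 14 members higher and 6 lower (the same adjusted over the list alone). Members of each bipolar list were higher at P30. Pan-bipolar genes had 17 of 19 members higher (the same adjusted over the list alone) (camera adjusted p = 4.6e-08, adjusted p = 0.047 with an estimated correlation). The mGluR6 cascade had 9 of 12 members higher and 2 lower (the same adjusted over the list alone). OFF-bipolar markers had 11 of 11 members higher (the same adjusted over the list alone) (camera adjusted p = 2.2e-04, adjusted p = 0.098 with an estimated correlation). Rod bipolar markers had 7 of 8 members higher (8 higher adjusted over the list alone), and cone bipolar markers 19 of 20 members higher (the same adjusted over the list alone). Trpm1, the cation channel of ON-bipolars, had 704 CPM at P30 (10.86 ± 2.26). Vsx1, a factor of cone bipolars, had 610.1 CPM at P7 (10.34 ± 1.79), and Tacr3, a receptor of OFF-bipolars, 68.9 CPM at P13 (10.28 ± 1.90). Prkca (chromosome 11, 107933387 to 108343928) was higher by 3.67 ± 0.59 and 3.64 ± 0.59 at P13 and P30. Lrit3, a leucine-rich repeat protein that the mGluR6 list includes, was lower in bipolars at P13 (-7.08 ± 1.40).

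Many members of adhesion and guidance families were higher in bipolars as well. Cadherins and protocadherins had 17 of 24 members higher and 2 lower (20 higher and 2 lower adjusted over the list alone) at P30. Their summed level at that age was lower in bipolars, at 1299 CPM against 1784 CPM in rods and 4877 CPM in cones. Ephrins and Eph receptors had 13 of 18 members higher (the same adjusted over the list alone). Leucine-rich repeat proteins had 26 of 37 members higher and 3 lower (28 higher and 3 lower adjusted over the list alone) (camera adjusted p = 3.6e-05, adjusted p = 0.047 with an estimated correlation). The neurexin, neuroligin, teneurin and latrophilin list had 21 of 23 members higher (the same adjusted over the list alone) (camera adjusted p = 4.8e-08, adjusted p = 0.04 with an estimated correlation). Immunoglobulin superfamily genes had 28 of 43 members higher and 4 lower (the same adjusted over the list alone) (camera adjusted p = 6.1e-04, adjusted p = 0.14 with an estimated correlation). Semaphorins and plexins had 19 of 29 members higher and 3 lower (21 higher and 3 lower adjusted over the list alone) (camera adjusted p = 0.0016, adjusted p = 0.098 with an estimated correlation). Slits, robos, netrins and Unc5 receptors had 8 of 14 members higher and 2 lower (9 higher and 3 lower adjusted over the list alone), and their list was not called (camera adjusted p = 0.061). Slit2, a secreted ligand of robo receptors, had 596, 483 and 335 CPM in bipolars (7.29 ± 1.75, 6.86 ± 1.75 and 7.73 ± 1.75). Robo2, a receptor for it, had 194, 239 and 187 CPM (6.50 ± 1.32, 7.57 ± 1.32 and 5.84 ± 1.32). Epha7, an Eph receptor, was higher at P30 (6.77 ± 1.18), and Ptprd, a receptor phosphatase that organises synapses, was higher at P7 (5.88 ± 1.03) and P13 (7.74 ± 1.03). Amigo2 had 552 CPM in bipolars at P30 with no reads in rods and 6.71 CPM in cones. Elfn1, which photoreceptors place at the synapse with bipolars, was lower (-6.20 ± 0.58 at P7). Of transmitter receptors at P30, GABA and glycine receptors had 18 of 21 members higher (the same adjusted over the list alone). Glutamate receptors had 17 of 23 members higher and 1 lower (the same adjusted over the list alone). The ribbon synapse list split, with 4 of 30 members higher and 12 lower (the same adjusted over the list alone) at P7 (camera adjusted p = 1.7e-06, adjusted p = 0.02 with an estimated correlation). Rims1, an active zone scaffold, was higher at P7 (9.73 ± 1.84), and Egflam, pikachurin of the photoreceptor synaptic cleft, was lower (-5.37 ± 0.33, -8.53 ± 0.33 and -5.94 ± 0.33). Wnt ligands had 4 of 7 members higher and 1 lower (5 higher and 1 lower adjusted over the list alone) at P30. Wnt receptors and planar polarity genes had 9 of 25 members higher and 3 lower (the same adjusted over the list alone) at P13. Wnt modulators and beta-catenin targets had 7 of 17 members higher and 1 lower (the same adjusted over the list alone) at P13. Ankrd6, a planar polarity protein, had 247 CPM in bipolars at P30 (8.31 ± 1.62).

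The immature neuron and growth cone list had 12 of 24 members higher and 1 lower (the same adjusted over the list alone) at P7 (camera adjusted p = 1.5e-06, adjusted p = 0.034 with an estimated correlation). Crmp1, a collapsin response mediator, stood at 5.11 ± 0.42, and Stmn1, stathmin, at 3.02 ± 0.40. Glycolysis genes had 5 of 23 members higher and 3 lower (the same adjusted over the list alone) at P7. Pfkp, a phosphofructokinase, was higher (2.69 ± 0.20), as was Tpi1, triosephosphate isomerase (2.82 ± 0.21). Hk2 was lower at P13 (-3.13 ± 0.30) and P30 (-4.75 ± 0.30). Nuclear respiratory chain genes had 23 of 43 members lower (the same adjusted over the list alone) at P7 (camera adjusted p = 8.6e-15, adjusted p = 0.19 with an estimated correlation). Casz1, a zinc finger regulator of photoreceptor fate, was lower at -5.48 ± 0.34, -7.62 ± 0.34 and -5.03 ± 0.34. Handling genes had 1 of 23 members higher and 7 lower (the same adjusted over the list alone) at P7 (camera adjusted p = 0.0066, adjusted p = 0.1 with an estimated correlation), as for Ier3 at -4.79 ± 0.28. Some markers of other retinal cells were higher in bipolars at P30. Müller glia markers had 13 of 17 members higher (15 higher adjusted over the list alone) (camera adjusted p = 1.2e-05, adjusted p = 0.098 with an estimated correlation). Amacrine markers had 11 of 14 members higher (12 higher adjusted over the list alone) (camera adjusted p = 6.1e-04, adjusted p = 0.18 with an estimated correlation). Microglia markers had 8 of 11 members higher (the same adjusted over the list alone) (camera adjusted p = 0.022, adjusted p = 0.28 with an estimated correlation). Vascular markers had 6 of 8 members higher (7 higher adjusted over the list alone) (camera adjusted p = 0.02, adjusted p = 0.14 with an estimated correlation). Horizontal cell markers had 4 of 5 members higher (the same adjusted over the list alone), and ganglion cell markers 1 of 10 members higher and 1 lower (the same adjusted over the list alone). Pigment epithelium markers had 3 of 8 members higher (5 higher adjusted over the list alone) at P13. Proliferation genes had 2 of 10 members higher and 2 lower (the same adjusted over the list alone) at P13, with a median that turned from positive to negative with quantile normalization. Of all 13405 tested genes, 2757 were higher and 1717 lower in bipolars at P13. Slc1a3, the glial glutamate transporter, had 8.87, 57.5 and 232 CPM in bipolars (4.71 ± 0.57 at P30). Prox1, found in both amacrine and bipolar cells, was higher at 6.48 ± 0.92, 7.87 ± 0.92 and 7.40 ± 0.92.

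For bipolars against photoreceptors, limma with Benjamini-Hochberg adjustment called 3048 genes at P7 (1559 higher and 1489 lower in bipolars). It called 4474 at P13 (2757 and 1717) and 4769 at P30 (3026 and 1743). Quantile normalization turned the splits to 1704 and 1914, 2162 and 2426, and 2572 and 3242, and median centring that at P7 to 1487 and 1584. The counts were 1952 and 1880 without bipolars P7 replicates 1 and 2, 2916 without bipolars P13 replicate 2 and 3178 without bipolars P30 replicate 2. With only the compared groups in the fit, Robo2 at P7 and Ankrd6 at P30 were not called.

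Among rods, cones and bipolars, genes called higher in 1 type than in each of the others at all 3 ages numbered 121, 87 and 275. Rod bipolars and cone bipolars did not enter these sets. Those of rods included Nt5e, an ectonucleotidase, and Esrrb, a nuclear receptor (155, 171 and 144 CPM for Nt5e at P7, P13 and P30). Those of cones included Lrfn2 and Adrb1, a beta-adrenergic receptor (369, 398 and 370.4 CPM for Adrb1). Those of bipolars included Nxph1, a neurexophilin, and Gpr179, an mGluR6 cascade protein (386, 459 and 548 CPM for Gpr179). Nt5e and Adrb1 were chosen after their values were seen. The count for rods was 78 without rods P7 replicate 1. That for bipolars was 133 without cones P7 replicate 2 and 140 and 139 without bipolars P7 replicates 1 and 2.

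Rod bipolars and cone bipolars were compared at P13 to separate the classes that contact rods and cones. Prkca had 5671 ± 886 CPM in rod bipolars and 246 ± 81.8 in cone bipolars (4.56 ± 0.68). Sebox, a homeobox gene of rod bipolars, was higher by 4.72 ± 0.53, and Ablim1, an actin-binding LIM protein, by 4.17 ± 0.33. Rod bipolar markers had 5 of 8 members higher (the same adjusted over the list alone) in rod bipolars (camera adjusted p = 1.0e-09, adjusted p = 0.0091 with an estimated correlation). Cone bipolar markers had 1 of 20 members higher and 2 lower (1 higher and 5 lower adjusted over the list alone) (camera adjusted p = 0.0065, adjusted p = 0.32 with an estimated correlation). Kcng4, a potassium channel subunit, had 2.65 and 227 CPM in rod and cone bipolars (-6.51 ± 1.20). Grm6 was high in both classes, at 3370.3 ± 228 and 1570.3 ± 12.01 CPM. Of the surface genes, Adrb1 (7.12 ± 1.06), Il1rap, the interleukin-1 receptor accessory protein (5.84 ± 0.89), and Amigo2, a leucine-rich repeat adhesion protein (3.36 ± 0.46), were higher in rod bipolars. Pcdh15 (-2.70 ± 0.21), Cadm3, a synaptic cell adhesion molecule (-2.43 ± 0.34), Igsf11 (-3.17 ± 0.27), and Plxna2, a semaphorin receptor (-2.42 ± 0.43), were lower. Cadherins and protocadherins had 3 of 24 members lower (1 higher and 7 lower adjusted over the list alone) (camera adjusted p = 9.4e-04, adjusted p = 0.12 with an estimated correlation). Semaphorins and plexins had 4 of 29 members lower (5 lower adjusted over the list alone) (camera adjusted p = 0.036, adjusted p = 0.32 with an estimated correlation). At the synapse, Snap25, a SNARE protein (1.54 ± 0.17), and Unc13b, a vesicle priming factor (1.67 ± 0.15), were higher in rod bipolars. Cplx4 (-3.20 ± 0.28), Gabrr3, a GABA receptor rho subunit (-5.30 ± 0.81), and Gabbr2, a GABA-B receptor subunit (-3.59 ± 0.59), were lower in rod bipolars. The immature neuron list had 5 of 24 members lower (6 lower adjusted over the list alone) in rod bipolars (camera adjusted p = 5.5e-04, adjusted p = 0.17 with an estimated correlation). Tubb3, a neuronal tubulin, stood at -4.98 ± 0.59 and Marcks at -1.82 ± 0.30. Glycolysis genes had 4 of 23 members lower (6 lower adjusted over the list alone) (camera adjusted p = 4.6e-06, adjusted p = 0.17 with an estimated correlation), with Ldha at -1.35 ± 0.21. Some microglia markers differed too, with 2 of 11 members lower (5 lower adjusted over the list alone) (camera adjusted p = 0.0017, adjusted p = 0.32 with an estimated correlation). In all, limma with Benjamini-Hochberg adjustment called 628 genes, 203 higher and 425 lower in rod bipolars. Quantile normalization gave 1078 genes (466 and 612) and log2(CPM + 1) gave 1251, while median centring moved the split to 310 and 352. Without cone bipolars replicate 1 the count was 361, and without replicate 2 297. Plxna2 was not called with precision weights (log2 fold change -2.27), and Plxna2 and Gabrr3 were not called with only the compared groups in the fit.

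Rods were compared between ages to follow their maturation. From P7 to P13 some members of the rod cascade rose. Gnat1, rod transducin, went from 124 ± 22.6 to 4881 ± 424 CPM (5.31 ± 0.32). Guca1b rose by 6.25 ± 0.48, Pde6a, a phosphodiesterase subunit, by 2.60 ± 0.48, Gngt1, rod transducin gamma, by 1.88 ± 0.33, and Rcvrn, recoverin, by 2.85 ± 0.44. The rod list had 8 of 18 members rising (10 rising adjusted over the list alone) (camera adjusted p = 1.1e-06, adjusted p = 0.47 with an estimated correlation). The shared list had 9 of 27 members rising (the same adjusted over the list alone) (camera adjusted p = 0.0018, adjusted p = 0.72 with an estimated correlation). The immature neuron list had 5 of 24 members falling (8 falling adjusted over the list alone) (camera adjusted p = 0.0022, adjusted p = 0.47 with an estimated correlation). Stmn1 changed by -4.16 ± 0.46 and Marcks, a growth cone protein, by -2.31 ± 0.30. The ribbon synapse list had 4 of 30 members rising and 1 falling (the same adjusted over the list alone) (camera adjusted p = 0.041, adjusted p = 0.47 with an estimated correlation). Cplx4 rose by 2.19 ± 0.28, while Cplx3 changed by -1.53 ± 0.22. Hk2 rose by 3.09 ± 0.34 and Slc16a1, a monocarboxylate transporter, by 3.98 ± 0.80. The adhesion molecules Cadm3 (-3.25 ± 0.34) and Igsf21 (-3.05 ± 0.28) fell. From P13 to P30 the nuclear respiratory chain had 22 of 43 members falling (the same adjusted over the list alone) (camera adjusted p = 2.3e-20, adjusted p = 0.77 with an estimated correlation). They included Ndufa1 (-2.94 ± 0.31), Cox6c (-2.52 ± 0.28) and Cox8a (-2.20 ± 0.27). The mitochondrial genome share went from 6.92% to 8.13%. Hk2 rose again (3.43 ± 0.34), as did Bsn and Pclo, scaffolds of the active zone (1.92 ± 0.29 and 1.41 ± 0.27). Snap25 (-1.68 ± 0.17, -0.96 with quantile normalization) and Cplx3 (-1.92 ± 0.22) fell. Tmsb10, a thymosin of immature neurons, fell (-4.86 ± 0.35), as did Nrep (-1.84 ± 0.20). The immature neuron list had 6 of 24 members falling (2 rising and 8 falling adjusted over the list alone) (camera adjusted p = 0.0083, adjusted p = 0.77 with an estimated correlation). In rods, limma with Benjamini-Hochberg adjustment called 1695 genes from P7 to P13 (754 rose and 941 fell) and 1614 from P13 to P30 (904 and 710). The second split turned to 436 and 634 with quantile normalization and 725 and 1050 with median centring, and the first to 941 and 830 with median centring. With only the compared groups in the fit limma called 0 and 0 genes, with 1923 and 2153 at an unadjusted p under 0.05. With array quality weights it called 326 and 401, and Pde6a, Gngt1, Rcvrn, Slc16a1 and Cplx4 were not called in the first interval. The first count was 1036 without rods P7 replicate 2 and 2742 without rods P13 replicate 1. The second was 3069 without rods P13 replicate 1 and 783 without rods P30 replicate 1.

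In cone libraries, Gnat1 rose from 5.11 ± 1.52 CPM at P7 to 215 ± 21.5 CPM at P13 (5.42 ± 0.32). It stood at 4.14% and 4.41% of its level in rods at these ages, so the rise followed that in rods. Whether RNA of rods carried into the cone libraries supplied this Gnat1 stays open. Drd4, a dopamine receptor, reached 229 ± 119 CPM (4.67 ± 0.61), and mt-Nd4, a mitochondrial genome transcript, rose by 2.17 ± 0.28 (0.17 with quantile normalization). Opn1sw and Arr3 were not called from P7 to P13, though their means in cones went from 3846 to 7232 CPM and from 2159 to 5999 CPM. The SE of Opn1sw is pooled over groups with low and uneven levels, such as rods at P7 with log2 CPM of 0.04 and 2.90. The missing call is therefore no sign that the level of P13 had been reached by P7. Opn1sw stood at 0.91 ± 0.86 (limma, Benjamini-Hochberg adjusted p = 0.88), and at -0.46 with quantile normalization. The rod list had 2 of 18 members rising (6 rising adjusted over the list alone) from P7 to P13 (camera adjusted p = 1.1e-11, adjusted p = 0.18 with an estimated correlation). From P13 to P30, Glul, glutamine synthetase of Müller glia, rose from 74.9 ± 28.1 to 319 ± 28.03 CPM (2.14 ± 0.30). Nupl1, a nucleoporin, fell from 16.05 ± 3.22 to 0.432 ± 0.554 CPM. The Müller glia list had 2 of 17 members rising (the same adjusted over the list alone) (camera adjusted p = 3.0e-04, adjusted p = 0.49 with an estimated correlation). In cones, limma with Benjamini-Hochberg adjustment called 59 genes from P7 to P13 (29 rose and 30 fell), against 1305 at an unadjusted p under 0.05. It called 429 from P13 to P30 (114 and 315). The first split turned to 20 and 19 with quantile normalization, 33 and 31 with median centring and 58 and 37 with log2(CPM + 1). With only the compared groups in the fit limma called 0 genes for each interval, with 1741 and 1614 at an unadjusted p under 0.05. The first count was 22 and 17 without cones P7 replicates 1 and 2. The second was 200 without cones P13 replicate 2 and 1261 without cones P30 replicate 2.

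In bipolars, some synaptic genes rose from P7 to P13, including Cplx4 (4.75 ± 0.28), Cacnb2, a calcium channel beta subunit (3.43 ± 0.30), Slc17a7, the vesicular glutamate transporter (2.46 ± 0.16) and Cacna1f (1.42 ± 0.18). The ribbon synapse list had 6 of 30 members rising and 2 falling (the same adjusted over the list alone) (camera adjusted p = 1.2e-06, adjusted p = 0.04 with an estimated correlation). Gabbr2 rose by 4.65 ± 0.59 and Cadm1, a synaptic adhesion molecule, by 2.18 ± 0.21. Tenm4 rose by 2.93 ± 0.33 and Pcdh15 by 1.60 ± 0.21. Dpysl3, a growth cone protein, fell (-1.86 ± 0.22). Some rod transcripts rose in the same interval, such as Gnat1 (4.11 ± 0.32) and Gngt1 (3.66 ± 0.33). The rod list had 7 of 18 members rising and 2 falling (8 rising and 4 falling adjusted over the list alone) (camera adjusted p = 0.0016, adjusted p = 0.51 with an estimated correlation). Some Müller glia markers rose too, such as Clu (3.16 ± 0.40) and Glul (1.81 ± 0.30). Their list had 4 of 17 members rising (6 rising adjusted over the list alone) (camera adjusted p = 4.8e-07, adjusted p = 0.12 with an estimated correlation). From P13 to P30, some cone transcripts rose in the bipolar libraries. Arr3 went from 0.242 to 51.99 CPM (9.76 ± 1.53), Opn1sw from 1.62 to 48.7 CPM (5.44 ± 0.86) and Pde6h, a cone phosphodiesterase subunit, changed by 5.36 ± 0.73. Arr3 had no reads in bipolars P13 replicate 2, so the size of its log2 fold change depends on the prior added before the log. The cone list had 4 of 14 members rising (5 rising adjusted over the list alone) (camera adjusted p = 5.0e-07, adjusted p = 0.018 with an estimated correlation). In cones at P30, Arr3 and Opn1sw stood at 11516 and 10333 CPM. Whether RNA of cones was carried into the bipolar libraries was not tested. The Müller glia list had 5 of 17 members rising (6 rising adjusted over the list alone) (camera adjusted p = 1.8e-10, adjusted p = 0.045 with an estimated correlation). Glul reached 3082 ± 919 CPM (2.76 ± 0.30) and Clu 697 ± 193 CPM (2.93 ± 0.40). The immature neuron list had 2 of 24 members falling (6 falling adjusted over the list alone) (camera adjusted p = 3.5e-07, adjusted p = 0.045 with an estimated correlation). The summed level of its members went from 13411 ± 572 CPM at P7 to 7687 ± 127 at P13 and 3988 ± 145 at P30. Immediate early and dissociation stress genes, a sign of handling, had 1 of 23 members rising (the same adjusted over the list alone) (camera adjusted p = 8.2e-05, adjusted p = 0.045 with an estimated correlation), and their sum went from 973 ± 220.0 CPM at P13 to 1465 ± 563 CPM at P30. In bipolars, limma with Benjamini-Hochberg adjustment called 400 genes from P7 to P13 (308 rose and 92 fell) and 250 from P13 to P30 (187 and 63). Quantile normalization gave 721 and 865 genes, and the second split turned to 430 and 435. The counts were 917 and 936 with log2(CPM + 1) and 1630 and 752 with array quality weights. A fit on the compared groups alone gave 1559 and 286. The first count was 214, 165, 228 and 176 without bipolars P7 replicates 1 and 2 and P13 replicates 1 and 2. The second was 64 without bipolars P13 replicate 2 and 74 without bipolars P30 replicate 2. With precision weights Gnat1, Gngt1 and Pcdh15 were not called in the first interval, nor Arr3 and Pde6h in the second. With only the compared groups in the fit, Arr3 and Opn1sw were not called in the second.

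**Figure D3:**
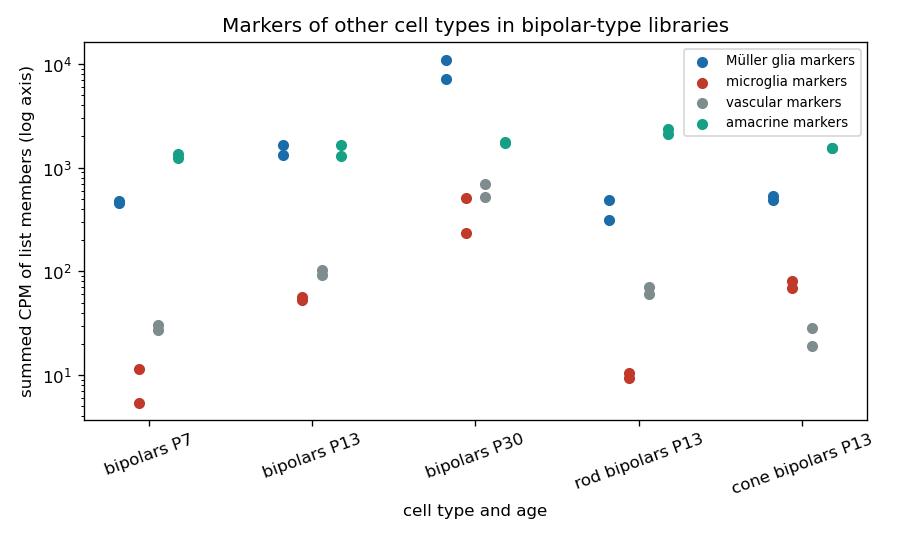
Summed CPM of the Müller glia, microglia, vascular and amacrine marker lists in each bipolar, rod bipolar and cone bipolar library, 1 point per library, on a log axis. The Müller glia sum in bipolars had a mean of 462 CPM at P7 and 9131 CPM at P30.

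Whether the change from P7 to P30 differed between cell types was tested as an interaction. For rods against cones, 1422 genes were called, 809 with the more positive change in rods and 613 with the more negative. That split turned to 355 and 492 with quantile normalization, 676 and 869 with median centring and 657 and 691 with log2(CPM + 1). With plain read totals it was 2105 and 232. Hk2 rose more in rods (4.61 ± 0.48). It went from 5.94 to 517 CPM against 211 to 799.5 CPM in cones. Cplx3 (-4.12 ± 0.31), Snap25 (-2.15 ± 0.24) and Nrxn3 (-5.67 ± 0.75) moved the other way. Nrxn3 stood at 145 and 8.59 CPM in rods at P7 and P30 and 124 and 273 CPM in cones. The nuclear respiratory chain had 22 of 43 members lower (28 lower adjusted over the list alone) in rods (camera adjusted p = 2.2e-21, adjusted p = 0.96 with an estimated correlation). They included Cox8a (-2.80 ± 0.38) and Ndufa1 (-2.61 ± 0.43). For bipolars against photoreceptors, 1492 genes were called, 920 with the more positive and 572 with the more negative change in bipolars. This split turned to 1177 and 1236 with quantile normalization and 779 and 833 with median centring. Müller glia markers had 7 of 17 members higher (8 higher adjusted over the list alone) in bipolars (camera adjusted p = 5.8e-06, adjusted p = 0.18 with an estimated correlation). Clu stood at 5.42 ± 0.49 and Glul at 2.96 ± 0.37. The ribbon synapse list had 7 of 30 members higher and 1 lower (9 higher and 1 lower adjusted over the list alone) (camera adjusted p = 0.0017, adjusted p = 0.18 with an estimated correlation). Cplx4 stood at 3.30 ± 0.35 and Slc17a7 at 2.28 ± 0.19. The immunoglobulin superfamily had 10 of 43 members higher and 1 lower (the same adjusted over the list alone) (camera adjusted p = 0.0018, adjusted p = 0.25 with an estimated correlation), with Cadm1 at 4.17 ± 0.26, and Hk2 had the more negative change in bipolars (-4.78 ± 0.42). These calls came from limma with Benjamini-Hochberg adjustment. The count for rods against cones was 616 without cones P7 replicate 1 and 837 without rods P30 replicate 1. That for bipolars was 775 and 766 without bipolars P7 replicates 1 and 2 and 807 without bipolars P30 replicate 2.

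Wnt5a, Wnt5b and Ryk were followed because, as known of the study, it went on to disrupt Wnt5 and its receptor Ryk. Wnt5a (chromosome 14, 28504750 to 28527448), a secreted Wnt ligand, had 143 ± 4.64 CPM in rod bipolars and 4.83 ± 0.00108 CPM in cone bipolars at P13. It had 2.75 ± 0.526, 13.6 ± 0.483 and 10.6 ± 6.86 CPM in bipolars. The highest mean in rods or cones was 8.19 ± 11.5 CPM, in rods at P13, with log2 CPM of 4.03 in replicate 1 and -4.12 in replicate 2. The difference between rod and cone bipolars was 4.88 ± 2.22 (limma, Benjamini-Hochberg adjusted p = 0.27). Across the alternatives its adjusted p ran from 9.4e-04 to 0.58 (limma, Benjamini-Hochberg). It was called with log2(CPM + 1), quantile normalization, array quality weights, precision weights and a fit on the compared groups alone. Wnt5b (chromosome 6, 119432531 to 119544347), the closest relative of Wnt5a, had 34.3 ± 1.60 CPM in rod bipolars and 1.05 ± 1.17 CPM in cone bipolars (5.71 ± 1.52). It was not called without rod bipolars replicate 1 or 2 (log2 fold change 5.76 and 5.66), without cone bipolars replicate 2 (4.19) or with only the compared groups in the fit. In bipolars Wnt5b had 15.4 ± 0.708, 8.75 ± 0.173 and 24.9 ± 0.408 CPM. At P7 it had 0.110 CPM in rods and 0.793 CPM in cones (6.46 ± 1.31). It had no reads in either at P13 and 0.00929 CPM in rods with no reads in cones at P30. Ryk (chromosome 9, 102834917 to 102908305), an atypical receptor kinase that binds Wnt5, had 99.8 ± 13.2, 101 ± 7.99 and 87.01 ± 3.05 CPM in rods and 60.9 ± 8.01, 54.1 ± 3.79 and 42.1 ± 10.2 CPM in cones. It had 71.7 ± 0.673, 40.9 ± 2.56 and 59.9 ± 19.6 CPM in bipolars, 26.1 ± 10.99 CPM in rod bipolars and 46.9 ± 0.419 CPM in cone bipolars. Ryk was called higher in rods than in cones at P30 (1.07 ± 0.28). It was not called without rods P30 replicate 1 (log2 fold change 1.03) or cones P30 replicate 2 (0.82), with array quality weights or with only the compared groups in the fit.

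**Figure D4:**
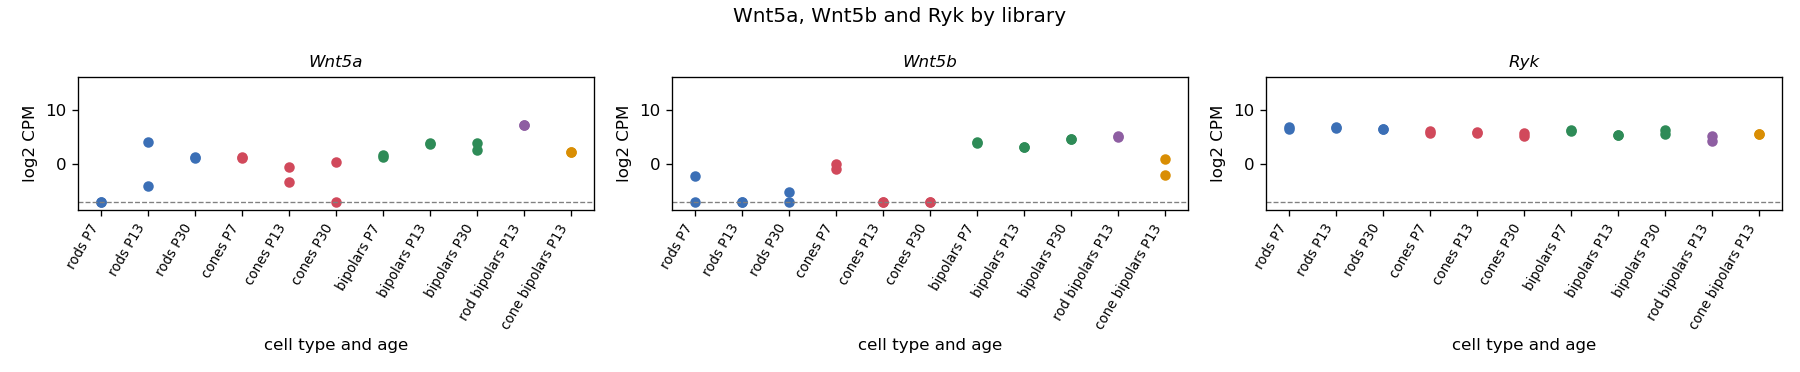
Deposited log2 CPM of Wnt5a, Wnt5b and Ryk in each library, 1 point per library, by cell type and age. Points at the dashed line have no reads. Wnt5a and Wnt5b are highest in rod bipolars, and Ryk is found in all 11 groups.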

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

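The tests of Müller glia RNA and of an even gain of all other cells in bipolar libraries, and all 4 tests of the mitochondrial share, were chosen only after the result was seen.

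The interaction tests found genes whose change from P7 to P30 differed between cell types. With limma and Benjamini-Hochberg adjustment 1422 genes differed between rods and cones (616 without cones P7 replicate 1 and 837 without rods P30 replicate 1). Hk2 had the more positive change in rods (log2 difference 4.61), and Cplx3 (-4.12), Snap25 (-2.15), Nrxn3 (-5.67), Cox8a (-2.80) and Ndufa1 (-2.61) the more negative. Between bipolars and photoreceptors 1492 genes differed (775 and 766 without bipolars P7 replicates 1 and 2, and 807 without bipolars P30 replicate 2). Clu (5.42), Glul (2.96), Cplx4 (3.30), Slc17a7 (2.28) and Cadm1 (4.17) had the more positive change in bipolars and Hk2 (-4.78) the more negative.

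Summed levels of glial and other non-neuronal markers were higher at P30 than at P7 in bipolar libraries, with summed CPM of Müller glia markers going from 462 at P7 to 9131 at P30, microglia from 8.41 to 375 and vascular cells from 28.6 to 609.7, while horizontal cells went from 536 to 303. The log2 rises of the lists differed by 6.30, from microglia to horizontal cells. Horizontal cell markers stood at 1413 CPM in rods at P7, and a level carried by other cells would hide a gain, as it would for pigment epithelium and ganglion cell markers, at 25.1 and 45.5 CPM in rods and 21.1 and 19.2 CPM in bipolars at P7. Rod genes went from 710 to 1707 CPM and amacrine markers from 1289 to 1749 CPM, log2 rises of 1.27 and 0.44. A part of these levels held by bipolars themselves would hide a gain in the same way. A lower share of bipolars with every other cell type gaining alike stays open. At P13 the Müller sum in rod or cone bipolars reached at most 34.6% of that in bipolars, which argues against expression by these bipolar classes at P13 and leaves P30 open, where neither class was collected. RNA of Müller glia cannot be told apart from expression by bipolars at P30, since either would raise these markers. In the test 100% of the 17 tested markers went up from P7 to P30 (11 called). Levels at P30 were 3082 CPM for Glul, 144 CPM for Apoe and 766 CPM for Rlbp1, and Dkk3 also belongs to the Wnt modulators. The labels name no gate that would remove glia, and a change with age in bipolars themselves was not tested at P30.

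Transcripts of the mitochondrial genome took a rising share of cone libraries, from 5.37% at P7 to 33.6% at P30. These shares were taken over plain reads, which the library scaling does not enter. They rose at least 4.65 times in every pair of cone libraries. The test of the library scaling used these same shares, so it repeats the rise and adds no support. The median log2 change of the nuclear respiratory chain genes in cones was 0.13, which argues against a parallel rise of the whole chain. The P30 to P7 ratio was 6.26 in cones, 3.03 in rods and 2.11 in bipolars. Over pairs of libraries it ran from 4.65 to 8.41 in cones and from 2.04 to 2.19 in bipolars. The lowest cone ratio was 2.13 times the highest of bipolars, which argues against an age effect of the same size in these cell types, and so in every cell type. It was 1.20 times the highest of rods (3.88), so an effect of the same size in cones and rods cannot be told apart with 2 libraries per group. A biological difference with age stays open and was not tested separately.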

How the results depend on the processing

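Precision weights, plain read totals and leaving out mitochondrial genome transcripts were tests chosen only after the result was seen. With no filter, a stricter filter, median centring, robust moderation, no fold threshold, the replicate block and mitochondrial genome transcripts left out, all 18 counts of called genes stayed within 1.5 times their main value. Other counts moved further, or their split by over 10 percentage points, and the cause was not tested. In brackets stand the genes called higher/lower and the range of the count with 1 library left out. The counts were, for rods against cones, 1718 (442/1276, 923 to 1623) at P7, 2843 (952/1891, 1937 to 3741) at P13 and 2684 (1338/1346, 1810 to 3112) at P30. They were, for bipolars against photoreceptors, 3048 (1559/1489, 1880 to 3101) at P7, 4474 (2757/1717, 2916 to 5150) at P13 and 4769 (3026/1743, 3178 to 5054) at P30 and for rod against cone bipolars, 628 (203/425, 297 to 643). Next were, for rods, 1695 (754/941, 1036 to 2742) from P7 to P13 and 1614 (904/710, 783 to 3069) from P13 to P30 and for cones, 59 (29/30, 17 to 60) from P7 to P13 and 429 (114/315, 200 to 1261) from P13 to P30. Then there were, for bipolars, 400 (308/92, 165 to 228) from P7 to P13 and 250 (187/63, 64 to 286) from P13 to P30 and for the change in rods against cones, 1422 (809/613, 616 to 2032). Also counted were, for the change in bipolars against photoreceptors, 1492 (920/572, 766 to 1907) and for enriched genes, 121 (78 to 119) of rods, 87 (60 to 107) of cones and 275 (133 to 351) of bipolars. With quantile normalization there were, for rods against cones, (574/834) at P7 and (976/1202) at P13, for bipolars against photoreceptors, (2162/2426) at P13 and (2572/3242) at P30 and for rods, 1070 (436/634) from P13 to P30. It gave, for cones, 39 from P7 to P13 and 177 (68/109) from P13 to P30, for bipolars, 721 (466/255) from P7 to P13 and 865 (430/435) from P13 to P30 and for rod against cone bipolars, 1078 (466/612). The rest were, for the change in rods against cones, 847 (355/492), for the change in bipolars against photoreceptors, 2413 (1177/1236) and for enriched genes, 430 of bipolars. With median centring there were, for rods against cones, (1381/1662) at P13, for rods, (725/1050) from P13 to P30 and for bipolars, (143/87) from P13 to P30. It gave, for rod against cone bipolars, (310/352), for the change in rods against cones, (676/869) and for the change in bipolars against photoreceptors, (779/833). With log2(CPM + 1) there were, for cones, 95 (58/37) from P7 to P13 and (172/250) from P13 to P30 and for bipolars, 917 from P7 to P13 and 936 from P13 to P30. It gave, for rod against cone bipolars, 1251, for the change in bipolars against photoreceptors, 2896 and for enriched genes, 178 of cones and 802 of bipolars. With no intensity trend there were, for cones, 96 from P7 to P13. With array quality weights there were, for rods against cones, 1295 at P13 and for rods, 326 from P7 to P13 and 401 from P13 to P30. It gave, for cones, 140 from P7 to P13 and 73 from P13 to P30 and for bipolars, 1630 from P7 to P13 and 752 from P13 to P30. The rest were, for the change in rods against cones, 836, for the change in bipolars against photoreceptors, 2413 and for enriched genes, 71 of rods and 506 of bipolars. With only the compared groups in the fit there were, for rods against cones, 491 at P13 and 863 at P30 and for rods, 0 from P7 to P13 and 0 from P13 to P30. It gave, for cones, 0 from P7 to P13 and 0 from P13 to P30, for bipolars, 1559 from P7 to P13 and for the change in rods against cones, 652. With precision weights there were, for cones, 172 from P7 to P13 and for enriched genes, 168 of cones and 702 of bipolars. With plain read totals there were, for rods against cones, (3090/833) at P30 and for bipolars against photoreceptors, (3833/1045) at P13 and (3853/1057) at P30. It gave, for rods, (470/1529) from P7 to P13 and (1184/498) from P13 to P30, for cones, 110 (22/88) from P7 to P13 and 972 (53/919) from P13 to P30 and for bipolars, (128/103) from P13 to P30. The rest were, for the change in rods against cones, 2337 (2105/232), for the change in bipolars against photoreceptors, (1309/327) and for enriched genes, 55 of cones. With mitochondrial genome transcripts left out there were, for bipolars against photoreceptors, (3450/1178) at P13 and for rods, (503/1363) from P7 to P13 and (1227/482) from P13 to P30. It gave, for cones, (17/37) from P7 to P13, for bipolars, (148/93) from P13 to P30 and for the change in rods against cones, (1047/430). These scalings moved the median log2 fold change of all genes by -0.41 to 0.65. Named genes were chosen partly because their calls held, so the counts that follow are no test of robustness. Of 193 called values of named genes, 191 kept the call with any 1 library left out. For single genes the direction and call were kept by 191 of 195 values with quantile normalization, 186 with array quality weights, 188 with precision weights and 135 with only the compared groups in the fit. Opn1sw in cones from P7 to P13, not called, reversed to -0.46 with quantile normalization. For rods and cones between ages, where limma called 0 genes with only the compared groups in the fit, there were 1923, 2153, 1741 and 1614 at an unadjusted p under 0.05. Deviations of libraries with the same replicate number correlated between -0.142 and 0.193 over 55 pairs of groups, across genes that are not independent, with 5 over 0.1. For genes at a mean log2 CPM of at least 3 they ran from -0.284 to 0.253. Not every pair was over 0.1, and the libraries were treated as sharing only a number. That rule would miss sharing among only some of the groups, so pairing there stays open. With the replicate block the counts were 1701, 2812 and 2653 for rods against cones at P7, P13 and P30, and no call of a named gene changed. The floor set by depth was highest in bipolars at P7, where a gene without reads could reach 0.0766 CPM. Genes without reads were nonetheless fewer there, at 452 and 686 in replicates 1 and 2. They numbered 2343 and 1791 in rods at P7, 1956 and 2463 in rods at P13, and 2384 and 1802 in cones at P30. Depth alone therefore did not set where low levels were lost.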

Other observations

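Shares and sums outside the comparisons differed between groups as well. The mitochondrial genome took 3.91%, 4.22% and 8.27% of reads in bipolars at P7, P13 and P30, 2.28% in rod bipolars and 2.63% in cone bipolars. The 10 highest genes of a library took 6.74%, 19.4% and 35.6% of reads in cones and 5.93%, 11.4% and 12.3% in rods. Amacrine markers summed to 1289 CPM in bipolars at P7 and 1749 CPM at P30, ganglion cell markers to 19.2 and 135 CPM, and pigment epithelium markers to 21.1 and 73.03 CPM.

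Rod transcripts were present in cone libraries and higher in CPM at P13 than at P7, with Gnat1 at 5.11 and 215 CPM. The test of this pattern was set before its result was seen. It took the 89 genes enriched in rods and above 100 CPM there at P13. After the median offset was taken off, 12.4% of them changed between P7 and P13 in cones by an amount that differed from rods by over 2 SE. That lay under the bound set for cones changing single rod genes, and above the 6.36% that chance would give. The bound was wrong, since genes kept for being higher in rods at every age leave out those that cones raised close to the level of rods, so this explanation stays open. The median cone to rod percentage was 23.4%, 19.5% and 25.4% at P7, P13 and P30. That of Gnat1 was 4.14%, 4.41% and 4.27%. RNA of rods carried into the cone libraries at the same percentage for all genes could exceed that of none of them. At P13 the lower and upper quartiles over the 89 genes were 7.76% and 29.0%. These values argue against such an even carry-over as the source of the median of 19.5% at P13. They do not cover Gnat1, which lay below the lower quartile. Whether carried RNA supplied Gnat1, or a part of the other levels, stays open.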
